A study of Rhodopseudomonas palustris with 28 samples.

How the data were processed

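The deposited table holds 1 value per gene and library for 4896 genes and 28 libraries of *Rhodopseudomonas palustris*, from 2 strains in 7 conditions with 2 libraries per group. Per the labels' protocols, cultures of 10 mL grew in light without oxygen at 30 °C with 40 mM carbon source, and with 10 mM bicarbonate on benzoate only. Precultures had 20 mM acetate, and cells were taken at an optical density (OD660) of 0.45 to 0.47. Ribosomal RNA was removed before library preparation. Per the submitters' processing notes, reads were examined with FastQC and trimmed with Trim Galore 0.6.2, and DESeq2 under R 3.6 was used. The values are estimated counts as deposited by the authors, and 98.4% of the values are not whole numbers. The aligner, the quantifier, the genome build and the annotation are not given in the sources used here. Gene names were those of the table, where 1428 genes carry a symbol besides the locus tag.

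Counts were rounded and fitted with edgeR 4.0.16 (quasi-likelihood) under R 4.3.3, with 1 mean per group and TMM scaling (factors 0.993 to 1.22 at high light and 0.715 to 0.875 at low light). Of the 4896 genes 65 had no count and 1 more was removed by filterByExpr (minimum count 10, minimum total 15), which left 4830. The fit had 14 residual and 4.09 prior degrees of freedom. The 16 comparisons were the strain effect averaged over the 7 conditions and in each of them, its interaction with condition on 6 degrees of freedom, the nitrogen condition, light and 3 carbon sources in the wild type, and the nitrogen and light interactions with strain. P-values are those of edgeR, adjusted by Benjamini-Hochberg within a comparison, and a gene was called at 0.05. Strain effects are deletion minus wild type on the log2 scale, with ± for the standard error. This error was derived from the test, as the absolute log2 fold change divided by the square root of its F statistic. It is not an error that the fit itself reports. CPM values use TMM-scaled totals and carry the SD over the libraries of a group. P-values measure the spread between libraries, and whether these came from separate cultures is not stated.

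Gene lists were fixed before the data were examined, as were the groups, comparisons, tests, naming rule and, but for those named as added, the alternatives. Of 24 lists 22 with at least 3 tested members were tested with camera of limma 3.58.1 in 15 comparisons, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and again with the correlation estimated from the residuals. Adjusted p-values span the lists of a comparison. Over the 22 lists and 15 comparisons 109 pairs were called with the preset and 17 with the estimated correlation. Beside the count of called members over all genes, the count adjusted over the list alone is given. The list of stable RNA could not be tested, since its 57 rRNA and tRNA genes hold 0 counts.

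Named genes had an adjusted p below 0.05, at least 10 CPM in the higher group and library values that did not overlap between groups, or the same sign in all 7 conditions for the average. The 10 largest changes per direction were named for the average strain effect, nitrogen and light, 5 per direction elsewhere, 5 by smallest p per interaction, and up to 4 members by smallest p per list. In the conditions the text gives fewer than 5 decreases, since regS and regR are among them. Groups follow the sample titles. For the 4 high-light succinate libraries the title names the medium without ammonium while the nitrogen-fixing characteristic says No.

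Alternatives were DESeq2 1.42.0, RLE size factors, library totals alone, no low-count filter, fits on only the libraries compared or only the wild type, replicate number as a block, leaving out each library in turn, and for light the comparison of low light with high-light malate. Leaving rRNA and tRNA out was planned and not run, as they hold no counts. Leaving out rnpB, tmRNA and ffs, and leaving out the benzoate libraries, were added after the data were seen. Where 1 library is left out, the other one of its group is assumed to vary as the other groups do. The procedure was tested on simulated data with 50 changed genes per fold. For the average strain effect all of them were recovered at 1.5-fold, 2-fold, 4-fold and 8-fold (100%), with 5.21% false among calls. For low-light succinate 62%, 90%, 98% and 100% were recovered, with 6.91% false among calls. All simulated groups shared 1 spread per gene, while replicate SDs of the real groups ran from 0.191 to 0.651. These rates therefore do not cover the unequal spread of the real groups. Camera gave p 1.79e-280 for a list of genes raised 1.5-fold to 8-fold and called 0 of 20 random ones. Simulated genes varied independently of each other, so this does not test whether the preset correlation is high enough.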

Results

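RNA abundance was measured by sequencing in *Rhodopseudomonas palustris*, a purple bacterium that grows on light and organic carbon without oxygen. The wild type was strain CGA010. It was compared with CGA2023, in which the neighbouring genes regS and regR are deleted. RegS is a sensor kinase and RegR its response regulator, a pair that responds to the redox state of the cell in this group of bacteria. Both strains grew in 7 conditions with 2 libraries per strain and condition, 28 libraries in 14 groups. PM was a mineral medium with ammonium, and NFM was the same medium without it. High light was 30 and low light 4 µmol photons per square metre and second. The conditions were PM with acetate, malate or benzoate and NFM with succinate or malate at high light, and NFM with acetate or succinate at low light. Library totals ran from 16.1 to 38.5 M estimated counts (median 28.4 M). The RNA of ribonuclease P, rnpB, took 1.78% to 5.94% of a library and the 10 most abundant genes together 14.1% to 26.2%. The 57 rRNA and tRNA genes of the table held 0 counts.

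The deleted genes were examined in each library first. In the 14 wild-type libraries regR lay between 233 and 508 CPM (counts scaled to library size) and regS between 74.9 and 142 CPM. In the 14 libraries of the deletion strain regR lay between 0.266 and 1.17 CPM (8 to 37 counts) and regS between 0.0327 and 0.347 CPM (1 to 13 counts). No library went against its strain label. Replicates of a group correlated at 0.989 or above across genes, except the benzoate libraries of the deletion strain at 0.959. The SD of their log2 difference was 0.651, against 0.191 to 0.324 in the other 13 groups.

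The series asks what the loss of RegS and RegR does to expression in light, so the strain effect was first averaged over the 7 conditions, with 14 libraries per strain. The deletion strain had far less RNA of RPA1515 (log2 fold change -4.03 ± 0.107 SE, 16.3-fold, adjusted p 3.01e-16), RPA0550 (-3.91 ± 0.0867) and RPA3881 (-3.75 ± 0.0436, 13.5-fold, adjusted p 1.06e-21). RPA3881 stood at 1614 ± 9.95 CPM (SD, n = 2) in the wild type and 71.7 ± 1.63 CPM in the deletion strain on NFM succinate. RPA1845, RPA1846 and RPA1848, of the run of neighbouring loci RPA1845 to RPA1849, fell (-3.18, -3.13 and -3.27). RPA2300 (-3.19) and RPA4683 (-3.16) fell as well. Increases were smaller. The largest was that of ictP (1.79 ± 0.0525, 3.46-fold, adjusted p 1.52e-15), followed by RPA4220 (1.76), RPA1741 (1.73), RPA3309 (1.69), RPA4219 (1.68), RPA3568 (1.67), RPA0472 (1.67), RPA0566 (1.66), RPA3308 (1.64) and RPA1739 (1.55). In all, 2392 of 4830 genes differed, 1241 higher and 1151 lower. Most differences were small (median absolute log2 fold change 0.26), and 169 genes changed at least 2-fold, 53 up and 116 down. The balance depends on the scaling, since library totals alone gave 1831 higher and 709 lower.

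A set of 68 genes was called in the same direction in each of the 7 conditions, 62 lower and 6 higher, where independent lists would share 0.000489 and 9.02e-05 genes. The 62 include regR and regS. Membership requires a call in low-light acetate, where 342 genes were called, or 172 with replicate number as a block. The set was not recomputed under the alternatives. Besides the genes above, the lower ones include mexC1 (-2.91 ± 0.0712) and its neighbour mexD2 RPA1498 (-2.60 ± 0.0345), named after parts of a multidrug efflux pump, and RPA3054 (-2.56 ± 0.044). Others are kefC (-1.67) and kefB (-0.87), named after potassium efflux proteins, hflK (-1.06) and hflC (-1.02), which act on a membrane protease in other bacteria, and the heat shock sigma factor gene rpoH (-0.76). The genes ilvG (-0.98) and ilvM (-0.97) carry names of a branched-chain amino acid enzyme. The higher ones were ictP, RPA0884 (1.35), RPA0883 (1.23), RPA4502 (0.80), RPA4000 (0.57) and RPA3482 (0.47). Genes of this paragraph outside the 10 largest changes were picked from the set after their values were seen. Across conditions, 3622 genes were called in at least 1 and 533 in opposite directions in different conditions.

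**Figure D1:**
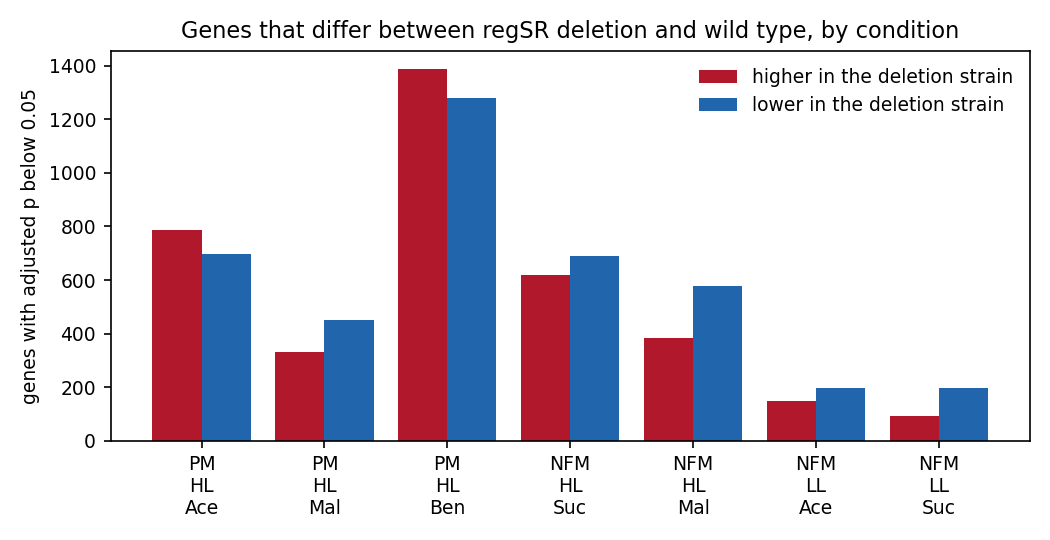
Number of genes (y axis) with adjusted p below 0.05 that were higher (red) or lower (blue) in the deletion strain than in the wild type, for each condition (x axis). The counts run from 91 higher and 197 lower in low-light succinate to 1387 higher and 1280 lower on benzoate, and with library totals alone the low-light succinate balance turns to 279 higher and 137 lower. This order rests in part on a spread shared by all groups. Fits of each condition's 4 libraries alone gave 671 genes in low-light succinate, 565 in low-light acetate, 525 on benzoate and 402 on PM malate. They gave 2420 on PM acetate, 1645 on NFM succinate and 1309 on NFM malate, which stayed above low light.

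Averaged over conditions, genes of respiratory complex I, which passes electrons between NADH and quinone, were lower in the deletion strain. Of 27 genes on the list, 19 fell and 8 were not called, the same adjusted over the list alone, with nuoM2 (-0.73 ± 0.0297), nuoF2 (-0.74), nuoH2 (-0.79) and nuoL2 (-0.68) in front (camera adjusted p 3.41e-07, or 0.176 with the estimated correlation). All 10 ATP synthase genes fell, 10 adjusted over the list alone, among them atpE (-0.43) and atpC (-0.43) (camera 0.00106, estimated 0.477). In bacteriochlorophyll and carotenoid synthesis 12 of 22 genes fell and none rose, 12 adjusted over the list alone, led by bchC (-0.53 ± 0.0416) and crtC (-0.46) (camera 0.00106, estimated 0.477). In the reaction centre and its inner antenna 4 of 5 genes fell, 5 adjusted over the list alone, with pufB (-0.37) and pufA (-0.36) (camera 0.0481, estimated 0.477). In the uptake hydrogenase cluster 13 of 21 genes rose and none fell, 13 adjusted over the list alone, with hypB (0.27), hypA (0.35) and hupI (0.48) (camera 0.00669, estimated 0.477). The list went the other way on PM malate, with hypD at -0.86 and hoxA at -0.77. Its member hupL went both ways. It was lower in the deletion strain on PM malate and on benzoate (106.9 and 59.21 against 191.7 and 183.7 CPM). In both low-light conditions it was higher (336.8 and 353.8 against 164.1 and 199.4 CPM with acetate), and libraries overlapped elsewhere. Of 18 iron and metal uptake genes 10 fell and 1 rose, also adjusted over the list alone, led by the exbD3 and exbB3 pair (-1.93 and -1.94), named after proteins that power uptake across the outer membrane (camera 0.00386, estimated 0.35). Among ribosomal protein genes 21 of 50 fell and 2 rose, also adjusted over the list alone, by little (rplF -0.22, rpsH -0.26, camera 0.00349, estimated 0.514). Their direction varied, with rplF at -1.04 on PM acetate and 0.47 in low-light succinate.

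The other lists did not pass the camera test on average with the preset correlation. With the estimated correlation none of the lists of the preceding paragraph passed. Called members were 1 higher and 9 lower of 28 for molybdenum nitrogenase, 0 and 3 of 13 for the alternative nitrogenases, 1 and 6 of 24 for nitrogen assimilation, 3 and 2 of 10 for the outer antenna LH2 and 4 and 6 of 17 for the Calvin cycle. They were 1 and 7 of 29 for benzoate degradation, 1 and 6 of 8 for acetate and glyoxylate metabolism, 1 and 6 of 12 for the citric acid cycle, and 6 and 5 of 18 for chaperones and proteases. For C4-dicarboxylate transport they were 1 and 4 of 8, for cytochromes c and bc1 1 and 4 of 10, for haem and cobalamin synthesis 1 and 4 of 27, for redox and oxygen regulators 0 and 0 of 7, and for flagella and chemotaxis 11 and 7 of 39. The median of nitrogen assimilation and of these last 5 lists turns from below to above 0 with library totals alone, by a shift that all genes share (median of all genes 0.0054 to 0.084). Of the 14 genes in the terminal oxidase list, where coxE and coxG may not be oxidase genes, 7 rose and 2 fell, but 3 rose and 6 fell without the benzoate libraries. Leaving these out also gave 6 higher and 4 lower for nitrogen assimilation, 4 and 4 for the Calvin cycle, 3 and 3 for C4-dicarboxylate transport, 5 and 5 for haem and cobalamin, 6 and 9 for flagella, 5 and 6 for chaperones and 2 and 1 for redox regulators. A list of photosynthesis regulators had 2 members, too few for the test. Of these, ppsR2, named after a repressor of photosynthesis genes, rose by 0.73 ± 0.0347 (adjusted p 2.53e-12), and RPA1537 by 0.22 (adjusted p 0.0242, or 0.0518 without deletion replicate 2 on PM malate).

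On PM acetate the deletion strain had less mexC1 (42.1 ± 1.26 CPM against 744 ± 84.5, SD, n = 2 each, -4.14 ± 0.199, adjusted p 2.12e-11), RPA2159 (-4.20) and RPA1847 (-4.15), besides regS and regR. It had more RPA0472 (2.77 ± 0.356, adjusted p 9.28e-06), RPA4220 (2.45), RPA0566 (2.43), RPA4221 (2.31) and coxM (2.16), a gene named after carbon monoxide dehydrogenase. Of 50 ribosomal protein genes 28 fell, 28 adjusted over the list alone, and none rose, with rplF at -1.04 ± 0.0741 and rpsH at -1.25 (camera 5.99e-14, estimated 0.115). In complex I 13 of 27 fell, 14 adjusted over the list alone, with nuoF2 at -1.17 and nuoH2 at -1.16 (camera 3.2e-05, estimated 0.168). Uptake hydrogenase genes rose in 12 of 21 cases, 12 adjusted over the list alone, with hupI at 1.35 (camera 0.00017, estimated 0.249). Iron and metal uptake genes fell in 11 of 18, 11 adjusted over the list alone, with exbB3 at -2.85 and exbD3 at -2.84 (camera 0.000205, estimated 0.115). Pigment genes fell in 8 of 22, led by bchC at -0.83 (camera 0.0471, estimated 0.611), and haem and cobalamin genes in 7 of 27, with 1 higher (camera 0.0239, estimated 0.611), the same counts adjusted over the list alone. In all 1484 genes differed, 786 higher and 698 lower, or 900 and 488 with library totals alone, and 2420 in a fit of the 4 libraries alone. Without wild-type replicate 1 the count was 917, without deletion replicate 1 958 and without deletion replicate 2 970.

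On PM malate the deletion strain had less RPA2122 (14.6 ± 2.09 CPM against 384 ± 74.7, SD, n = 2 each, -4.72 ± 0.325, adjusted p 2.76e-09), RPA2379 (-4.53) and RPA4683 (-4.50), besides regS and regR. The largest increases were in the form I Rubisco genes cbbS (3.50 ± 0.686, adjusted p 0.00124), cbbX (3.36) and cbbL (3.14) and in RPA1562 (2.29), but their size rests on 1 library. The CPM of cbbS in the deletion strain was 45.8 ± 55.7 (SD, n = 2), and without deletion replicate 2 its change was 0.67 (adjusted p 0.213), that of cbbX 0.42 (adjusted p 0.384), that of RPA1562 0.16 (adjusted p 0.823) and that of cbbL, still called, 0.94 (adjusted p 0.0309). RPA3568 rose by 2.14 ± 0.296. Anaerobic benzoate degradation genes, here in cells without benzoate, fell in 13 of 29 cases, 13 adjusted over the list alone, with hbaG at -1.02 ± 0.0961, hbaH at -1.07 and hbaF at -1.23 (camera 5.88e-06, estimated 0.00126). Uptake hydrogenase genes fell in 10 of 21, 16 adjusted over the list alone, with hypD at -0.86 and hoxA at -0.77 (camera 1.15e-07, estimated 0.0977). In complex I 11 of 27 fell, 11 adjusted over the list alone, with nuoM2 at -0.99 (camera 1.73e-05, estimated 0.161). Of 18 iron and metal uptake genes 5 fell and 2 rose, with exbB3 at -3.87 (camera 0.0295, estimated 0.399). Molybdenum nitrogenase genes rose in 3 of 28, nifX, nifB2 and nifA by 0.53, 1.12 and 0.35, each lost without wild-type replicate 1 or 2 (camera 0.0295, estimated 0.64). Without deletion replicate 2 nifB2 was at 0.29 (adjusted p 0.615) and nifA at 0.21 (adjusted p 0.314). For iron uptake and nitrogenase the counts adjusted over the list alone were the same. In all 785 genes differed, 333 higher and 452 lower, or 440 and 359 with library totals alone, 402 in a fit of the 4 libraries alone and 520 without wild-type replicate 1.

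On PM benzoate the deletion strain had more RPA0566 (921 ± 130 CPM against 28.0 ± 0.764, SD, n = 2 each, 5.04 ± 0.227, adjusted p 8.62e-12) and RPA3309 (4.67). LH2 antenna genes of a cluster that low light induces in the wild type rose 23.1-fold (pucBc, 4.53 ± 0.279), 19.7-fold (pucAd, 4.30) and 19.5-fold (pucBd, 4.29). In single libraries pucBd stood at 3900 and 4516 CPM in the deletion strain and at 249 and 181 CPM in the wild type. Of the 10 LH2 genes 3 rose and 5 fell, 3 and 6 adjusted over the list alone, with pucBe at -1.33, and the list as a whole was not called (camera 0.805). RPA4220 rose by 4.52, while RPA1515 (-4.66 ± 0.285), RPA1831 (-4.38) and RPA2300 (-4.15) fell. Genes of the terminal oxidase list, of which coxE and coxG may not be oxidase genes, rose in 13 of 14 cases, 14 adjusted over the list alone, with fixI at 1.30 ± 0.126, fixG at 2.11 and fixP at 2.41 (camera 0.000117, estimated 0.543). The list's median was 1.89, or 2.43 without deletion replicate 1 and 0.85 without replicate 2. All 10 ATP synthase genes fell, 10 adjusted over the list alone, with atpB at -1.63 (camera 0.000202, estimated 0.543). In complex I 18 of 27 fell and 2 rose, also adjusted over the list alone (camera 0.000537, estimated 0.543). In ribosomal proteins 20 of 50 genes fell and 3 rose, in haem and cobalamin 14 of 27 fell and 3 rose, and in pigments 10 of 22 fell and 3 rose, with 18, 16 and 10 lower and 3 higher in each adjusted over the list alone (camera 0.041, 0.0228 and 0.041, estimated 0.543 for each). Flagellar and chemotaxis genes rose in 18 of 39 and fell in 6, also adjusted over the list alone, with cheR3 at 0.90 (camera 0.041, estimated 0.543). In all 2667 genes differed, 1387 higher and 1280 lower. The benzoate replicates of the deletion strain differed most of all groups, and the 4 benzoate libraries fitted alone gave 525 genes. In that fit 1 oxidase, 2 ATP synthase, 3 complex I, 1 ribosomal, 1 pigment and 0 haem and cobalamin or flagellar genes were called, while 3 LH2 genes were higher. Without deletion replicate 1 or 2 the lower ribosomal genes were 25 or 12.

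On NFM succinate the deletion strain had less RPA0550 (-4.83 ± 0.231, adjusted p 1.7e-11), RPA3881 (-4.49 ± 0.119, 22.5-fold) and RPA1515 (-4.49), besides regS and regR. It had more hpd (256 ± 21.6 CPM against 38.7 ± 2.31, SD, n = 2 each, 2.73 ± 0.188), named after a tyrosine breakdown enzyme, RPA3565 (2.58), ictP (2.53), aroG1 (2.49 ± 0.13), named after the first enzyme of aromatic amino acid synthesis, and RPA0579 (2.39). LH2 genes rose in 7 of 10 cases, 7 adjusted over the list alone, with pucBd at 2.10 ± 0.265, pucAd at 2.08 and pucBc at 1.64 (camera 0.000994, estimated 0.39). In complex I 18 of 27 fell, 21 adjusted over the list alone, with nuoF2 at -1.37 and nuoM2 at -1.26 (camera 2.33e-10, estimated 0.0506). Iron and metal uptake genes fell in 9 of 18, 10 adjusted over the list alone with 1 higher, led by exbD3 at -3.18 and fecR4 at -1.52 (camera 3.21e-05, estimated 0.0522). Pigment genes fell in 11 of 22 with crtC at -0.74, and ATP synthase genes in 7 of 10 with atpI at -0.61 (camera 0.00168 and 0.00294, estimated 0.736 for each), the same counts adjusted over the list alone. Of 8 acetate and glyoxylate genes 5 fell and 1 rose, also adjusted over the list alone (camera 0.00921, estimated 0.183). Of these phaA (-1.52) and phaC RPA2790 (-1.68) lie near phaE, and these symbols are used both for storage polymer synthesis and for a potassium-proton antiporter, which the table does not resolve. In all 1308 genes differed, 617 higher and 691 lower, or 992 and 501 with library totals alone, which moves the median of all genes from 0.017 to 0.13.

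On NFM malate the deletion strain had less RPA4683 (15.2 ± 0.485 CPM against 587 ± 81.3, SD, n = 2 each, -5.27 ± 0.212, adjusted p 9.15e-13), RPA0746 (-4.34) and RPA0745 (-4.26), besides regS and regR. It had more aroG1 (2.46 ± 0.129), RPA1704 (2.37), cobT1 (2.05 ± 0.231), RPA1703 (2.19) and RPA2613 (1.96). Without wild-type replicate 1 the last pair missed the threshold (adjusted p 0.0685 and 0.101), and RPA2613 also without deletion replicate 2 (adjusted p 0.152). Molybdenum nitrogenase genes, which serve growth on N2, fell in 20 of 28 cases and 1 rose, 21 and 2 adjusted over the list alone, with nifN at -0.89 ± 0.108, nifB at -1.11 and nifU at -1.43 (camera 1.16e-07, estimated 0.0952). Haem and cobalamin genes rose in 12 of 27 and fell in 2, 13 and 2 adjusted over the list alone, with cobO at 0.76 (camera 0.000313, estimated 0.51). Benzoate degradation genes fell in 7 of 29, 11 adjusted over the list alone, with hbaH at -0.97 and hbaG at -0.87 (camera 0.00178, estimated 0.0215). Iron and metal uptake genes fell in 9 of 18 and rose in 1, 9 and 2 adjusted over the list alone, with exbB3 at -2.36 (camera 0.00807, estimated 0.285), and ATP synthase genes fell in 3 of 10, 4 adjusted over the list alone (camera 0.0193, estimated 0.681). In complex I 10 of 27 fell, 10 adjusted over the list alone (camera 0.0409, estimated 0.577), and the list's median turns from -0.059 to 0.083 with library totals alone, by the shift that all genes share. Of the hydrogenase genes 2 of 21 rose, hypF and hoxA, both lost without wild-type replicate 1 or either deletion replicate, and none adjusted over the list alone (camera 0.0306, estimated 0.577). In all 961 genes differed, 382 higher and 579 lower, or 793 and 376 with library totals alone, which moves the median of all genes from -0.014 to 0.13. The count was 566 without wild-type replicate 1 and 552 without deletion replicate 2.

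In low-light acetate the deletion strain had less RPA1515 (3.39 ± 0.326 CPM against 54.2 ± 8.04, SD, n = 2 each, -4.00 ± 0.295, adjusted p 2.71e-08), RPA0550 (-3.45) and RPA3881 (-2.70), besides regR and regS. It had more RPA1441 (1.43 ± 0.237), ictP (1.32), RPA1442 (1.14), RPA0883 (1.13) and RPA4502 (1.09). Uptake hydrogenase genes rose in 9 of 21 cases, 15 adjusted over the list alone, with hupI at 0.88, lost without any 1 of the 4 libraries (camera 1.45e-08, estimated 0.138). Genes that fell were 5 of 22 pigment genes (bchC -0.82), 2 of 5 reaction centre genes (pufB -0.78) and 4 of 10 LH2 genes (pucBe -0.72). Adjusted over the list alone these were 10, 5 and 7 (camera 3.92e-06, 0.000164 and 6.65e-05, estimated 0.299, 0.196 and 0.288). Of 27 complex I genes 4 fell, 7 adjusted over the list alone (camera 0.00738, estimated 0.359). Flagellar and chemotaxis genes rose in 3 of 39, cheR1, cheA1 and motB2, each lost without any 1 of the 4 libraries (camera 0.00323, estimated 0.298), and of 18 chaperone and protease genes only rpoH was called, at -0.67 (camera 0.0373, estimated 0.359), the same counts adjusted over the list alone. In all 342 genes differed, 147 higher and 195 lower, or 172 with replicate number as a block and 565 in a fit of the 4 libraries alone. Without wild-type replicate 1 or 2 the counts were 104 and 194, and without deletion replicate 1 or 2 they were 152 and 86.

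In low-light succinate the deletion strain had less RPA1422 (11.9 ± 6.92 CPM against 315 ± 86.1, SD, n = 2 each, -4.72 ± 0.64, adjusted p 6.6e-05), RPA1421 (-4.48) and ybdE (-4.43), 3 adjacent loci, besides regS and regR. It had more RPA1738 (2.82-fold, adjusted p 3.42e-07), RPA1739 (1.33), RPA1740 (1.31) and RPA1741 (1.34), also adjacent, and ictP (1.42). The call of RPA1741 was lost without any 1 of the 4 libraries (adjusted p 0.141 and 0.181 without wild-type replicate 1 and 2, 0.0817 and 0.124 without deletion replicate 1 and 2). Uptake hydrogenase genes rose in 8 of 21 cases, 11 adjusted over the list alone, with hypB at 0.54 ± 0.0952 (camera 1.25e-06, estimated 0.0798). Among ribosomal protein genes 11 of 50 rose, 28 adjusted over the list alone, with rplF at 0.47 (camera 1.41e-14, estimated 0.0558). In complex I 7 of 27 fell, 13 adjusted over the list alone, with nuoE2 at -0.86 (camera 5.65e-08, estimated 0.0558). Of 13 alternative nitrogenase genes 4 fell, vnfH (-0.89) and vnfA (-1.03) of the vanadium enzyme among them, 6 adjusted over the list alone (camera 0.00197, estimated 0.137). Benzoate degradation genes rose in 3 of 29, 3 adjusted over the list alone, with hbaG at 0.43, lost without wild-type or deletion replicate 1 (camera 0.000143, estimated 0.00816). Reaction centre genes fell in 3 of 5, pigment genes in 5 of 22 and LH2 genes in 0 of 10, or 5, 8 and 1 adjusted over the list alone (camera 0.000143, 0.000143 and 0.00492, estimated 0.0798, 0.333 and 0.333). Of 18 chaperone and protease genes rpoH (-0.82) and clpX (-0.43) fell, clpX not without wild-type replicate 2 or either deletion replicate, 4 adjusted over the list alone (camera 0.00463, estimated 0.167). In all 288 genes differed, 91 higher and 197 lower, or 279 and 137 with library totals alone, which moves the median of all genes from 0.0067 to 0.14. A fit of the 4 libraries alone gave 671. Without wild-type replicate 1 or 2 the counts were 173 and 147, and without deletion replicate 1 or 2 they were 174 and 153.

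**Figure D2:**
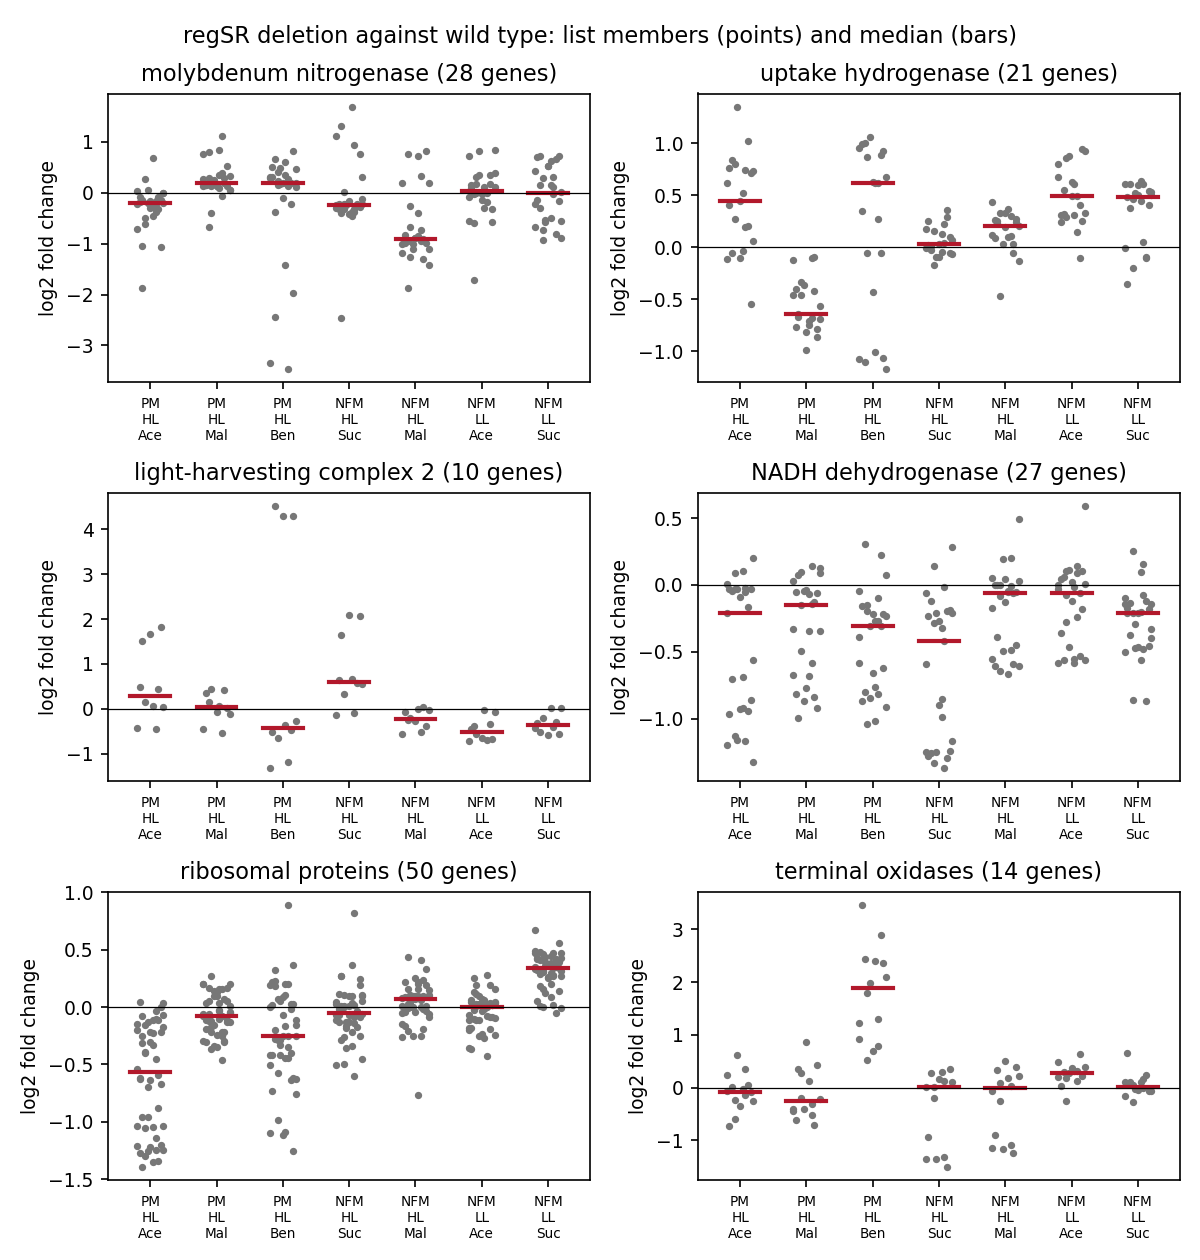
Log2 fold change of the deletion strain against the wild type (y axis) for the members of 6 fixed gene lists (points) and their median (red bars) in each condition (x axis). The median of molybdenum nitrogenase lies below 0 on NFM malate and that of terminal oxidases above 0 on benzoate (adjusted p 0.0952 and 0.543 with an estimated correlation), and with library totals alone the medians of complex I and terminal oxidases on NFM malate, ribosomal proteins on NFM succinate and molybdenum nitrogenase in low-light succinate turn from below to above 0 with the shift that all genes share, as does that of ribosomal proteins in low-light acetate in the other direction with RLE size factors.

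Whether the strain effect depends on the condition was tested directly. In the 6-degree-of-freedom test 2643 of 4830 genes differed, and 2573 without the benzoate libraries. RPA0745 had the highest F (212, adjusted p 4.52e-12). RPA0745 fell most on NFM malate (-4.26), PM malate (-3.48) and low-light succinate (-3.19), less on NFM succinate (-1.91), low-light acetate (-0.64) and PM acetate (-0.40), and was not called on benzoate (0.20 ± 0.118). Its neighbour RPA0744 (F 107) fell most in the same 3 conditions (-4.16, -3.18 and -3.43), less on NFM succinate (-1.66) and low-light acetate (-0.76), and was not called on PM acetate or benzoate. RPA1685 (F 107) fell by 2.83 on PM acetate and was not called in low-light acetate (-0.29) or low-light succinate (-0.28). The gene aroG1 (F 93.3) rose on NFM succinate (2.49) and NFM malate (2.46), less on PM malate (1.155) and benzoate (0.71), and fell in low-light acetate (-0.49). RPA4682 (F 88.3) fell in all 7 conditions, most on NFM malate (-3.09) and least in low-light acetate (-0.39). These calls in low-light acetate and that of RPA0745 on PM acetate are each lost without at least 1 of the 4 libraries. Across genes without regR and regS, the strain effects of any 2 conditions, which share no library, had a Pearson r of 0.265 (benzoate and low-light succinate) to 0.78 (NFM succinate and NFM malate). Spearman's rho over all genes ran from 0.0995 (PM malate and low-light acetate) to 0.646 (NFM succinate and NFM malate). In that last pair 231 genes were higher in both and 415 lower in both, where independent lists would share 48.8 and 82.8, and 6 went opposite ways. Genes are not independent replicates.

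The nitrogen condition was compared in the wild type as NFM malate against PM malate. Nitrogenase genes made up the largest increases. The structural genes nifD (5556 ± 576 CPM against 26.6 ± 3.63, SD, n = 2 each, 7.71 ± 0.264, 209-fold, adjusted p 2.91e-14), nifK (7.57, 190-fold) and nifH4 (6.88, 118-fold) encode the molybdenum enzyme that reduces N2. They were joined by fixC (7.41), nifV (7.08), RPA4627 (6.71), nifE (6.69), nifS2 (6.59), RPA4626 (6.51) and nifX (90.6-fold), all from a single stretch of loci. In total 23 of 28 list members rose and 1 fell, also adjusted over the list alone, with a median of 5.99 (camera 1.62e-36, estimated 2e-04). Alternative nitrogenase genes rose in 8 of 13 cases, 8 adjusted over the list alone, but far less, with vnfH at 1.17 and vnfA at 1.56 (camera 0.000112, estimated 0.0584). Nitrogen assimilation genes rose in 10 of 24 and fell in 3, 11 and 4 adjusted over the list alone, led by the ammonium sensor and transporter genes glnK2 (5.70 ± 0.284) and amtB2 (5.27), then glnB (2.92) and the glutamine synthetase gene glnA (1.60) (camera 0.0095, estimated 0.0732). LH2 genes rose in 5 of 10, 7 adjusted over the list alone, with pucBb at 0.71 (camera 0.0126, estimated 0.334).

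The largest decreases in the same comparison were in cobalamin genes, cobQ2 (-2.75 ± 0.343), cobT1 (-2.70) and cobF (-1.91), with RPA2095 (-2.81) beside them, and in the adjacent loci RPA3293 to RPA3297, of which RPA3297 went from 9068 ± 1080 to 1504 ± 236 CPM (-2.59 ± 0.44, adjusted p 0.000239). RPA3296 (-2.60), RPA3295 (5.67-fold lower), RPA3293 (-2.38) and RPA3294 (-2.34) fell too. The fall of nrd (-1.82) rests on single libraries, at -0.83 (adjusted p 0.211) without PM replicate 1 and -1.65 (adjusted p 0.0644) without NFM replicate 1. Haem and cobalamin genes fell in 19 of 27 cases, 19 adjusted over the list alone (camera 3.1e-09, estimated 0.0639). In complex I 21 of 27 fell, 22 adjusted over the list alone with 1 higher, with nuoM2 at -1.14 (camera 1.12e-11, estimated 0.0177). Flagellar and chemotaxis genes fell in 23 of 39, 24 adjusted over the list alone with 1 higher, with flhB at -1.01 (camera 6.42e-06, estimated 0.0497). Among ribosomal protein genes 23 of 50 fell, 24 adjusted over the list alone with 5 higher (camera 0.000172, estimated 0.334). Benzoate degradation genes fell in 9 of 29 with pimD at -0.69 (camera 0.00376, estimated 0.0187), and C4-dicarboxylate transport genes in 5 of 8 with dctQ1 at -0.95 (camera 0.0146, estimated 0.081), the same counts adjusted over the list alone. In all 1475 genes differed, 683 higher and 792 lower. The count was 935 without PM replicate 1 and 864 without NFM replicate 1.

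Whether this response differs between strains was tested as an interaction on the same libraries and those of the deletion strain. On malate, molybdenum nitrogenase genes responded less in the deletion strain, with 18 of 28 lower, 19 adjusted over the list alone, and a median of -1.07 (camera 5.04e-18, estimated 0.00733). Examples are nifX (-1.52 ± 0.199, adjusted p 0.000326), nifU (-1.76), nifN (-1.02) and fixB (-1.59). The number of lower genes was 16 without deletion replicate 1 on NFM malate and 9 without replicate 2. This lesser response was tested on malate alone. On NFM succinate nifD stood at 7360 and 4932 CPM in the deletion strain and 6759 and 7793 CPM in the wild type. In low-light acetate it stood at 5141 and 5741 against 3310 and 5251 CPM, so the strains overlapped in both conditions. In low-light succinate it was lower, at 7894 and 8258 against 10210 and 13060 CPM. The interaction of hydrogenase genes was positive in 8 of 21 cases, 11 adjusted over the list alone (median 0.82, camera 2.09e-15, estimated 0.00829). Among them hypD (1.10 ± 0.13, adjusted p 0.000147) fell by 0.86 in the deletion strain on PM malate, and hoxA (1.03) fell by 0.77 there. RPA4099 (2.67) and RPA4098 (3.16) were lower in the deletion strain on PM malate (-2.56 and -2.84) and not called on NFM malate. The opposite sign was found for mexD2 RPA2736 (-0.93 ± 0.111). In haem and cobalamin synthesis, which fell in the wild type, the interaction was positive for 8 of 27 genes and negative for 1, 11 and 1 adjusted over the list alone, with cobU at 1.58 (camera 4.05e-07, estimated 0.252), and for 4 without deletion NFM replicate 2. For complex I 2 of 27 genes were higher, nuoM2 and nuoL2, the latter lost without wild-type NFM replicate 1 or 2, 3 adjusted over the list alone (camera 0.0145, estimated 0.542), and for ribosomal proteins none of 50 was called, 2 higher and 1 lower adjusted over the list alone (camera 0.0349, estimated 0.685). In all 193 genes were called, 83 higher and 110 lower, or 109 and 59 with library totals alone and 314 with DESeq2. Without wild-type PM replicate 1 or 2 the count was 91 or 119, without wild-type NFM replicate 1 it was 91, and without deletion NFM replicate 1 or 2 it was 104 or 69.

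**Figure D3:**
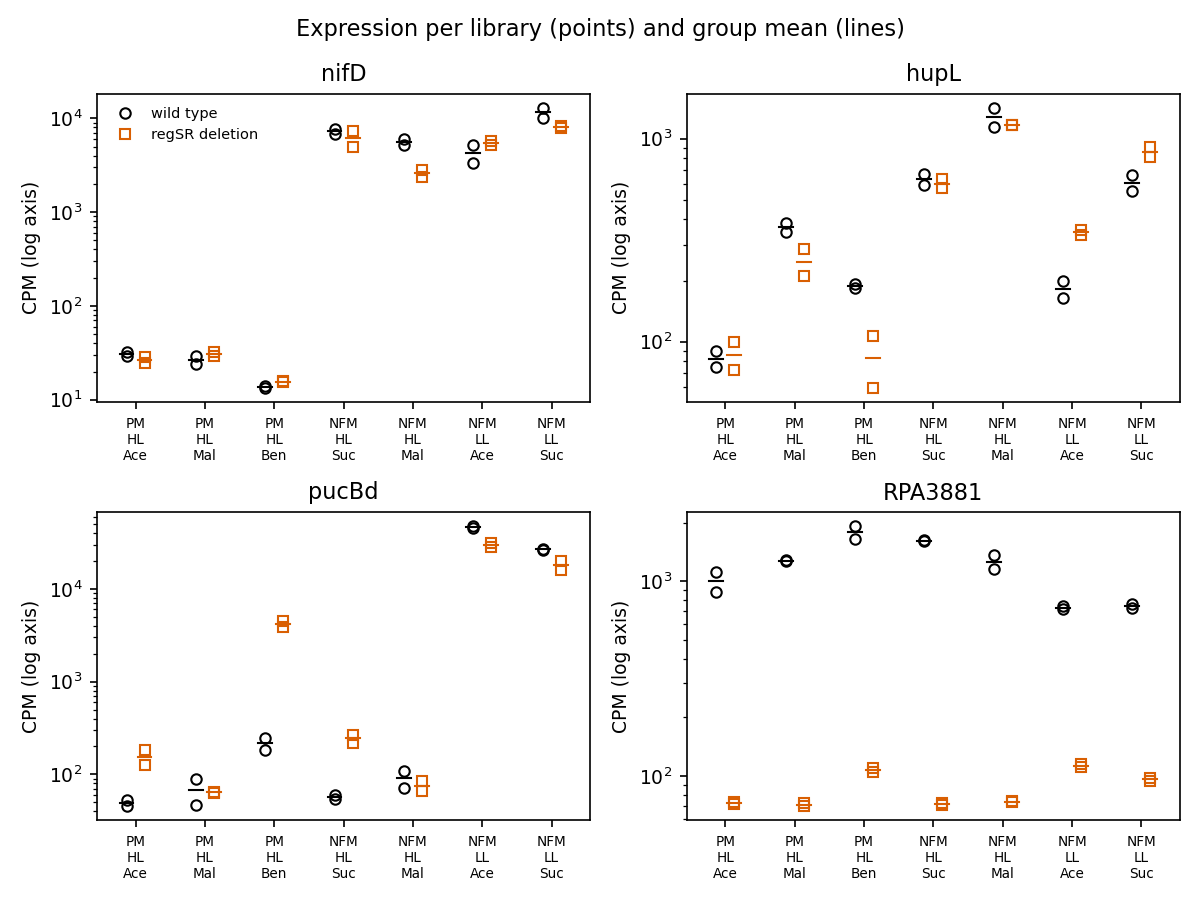
CPM on a log axis (y axis) of nifD, hupL, pucBd and RPA3881 in each library (points) of the wild type (black circles) and the deletion strain (orange squares), with group means (lines), by condition (x axis). RPA3881 is lower in the deletion strain in each condition, and pucBd in the benzoate libraries lies at 3900 and 4516 CPM in the deletion strain and 249 and 181 CPM in the wild type.

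Light was compared in the wild type as low-light against high-light succinate. The titles of the high-light libraries name the NFM medium, while their nitrogen-fixing characteristic says No. In those 2 libraries nifD stood at 7276 ± 731 CPM (SD, n = 2), against 5149 and 5963 CPM on NFM malate and 13.36 to 31.99 CPM in the wild-type PM libraries, so RNA of nifD was at the level of the medium in the titles. Low light raised LH2 antenna genes most, pucBc from 35.7 ± 3.65 to 17130 ± 802 CPM (8.91 ± 0.341, 480-fold, adjusted p 1.82e-12), pucBd 468-fold, pucAd 390-fold and their neighbour RPA3011 272-fold (8.09). LH2 copies are similar to each other, and how reads shared between copies were counted is not stated, so values of single copies are uncertain. RPA1422 (6.92), RPA1421 (5.49), RPA1001 (4.99), RPA4610 (4.86), ohr (4.86 ± 0.513), named after peroxide resistance, and RPA1562 (4.85) also rose. Decreases were led by RPA2321 (-4.27 ± 0.661), RPA2320 (-4.17), RPA1205 (-3.98), RPA1206 (-3.94), RPA2379 (-3.75) and RPA2378 (-3.48), with RPA2307 at -3.44. RPA3295 (-3.78), RPA3294 (-3.67) and RPA3293 (-3.53) fell too, but RPA3294 and RPA3293 were not called when low-light succinate and acetate were compared with high-light malate, 3 groups labelled as nitrogen-fixing (-0.33 and -0.28, adjusted p 0.205 and 0.223). Unlike nifD, these 3 loci stood in high-light succinate (1391, 967.5 and 1235 CPM) near PM malate (1234, 769.4 and 1053 CPM). On NFM malate they stood at 217.7, 151.8 and 201.8 CPM. A part of the nitrogen condition or of the carbon source in these changes was not told apart from light.

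By list, 8 of 10 LH2 genes rose in low light (camera 1.32e-05, estimated 0.241), all 5 reaction centre genes rose with puhA at 1.62 ± 0.123 (camera 0.00911, estimated 0.241), and none of either list fell, also adjusted over the list alone. Against high-light malate the counts were 8 and 5. Terminal oxidase genes rose in 9 of 14 cases and fell in 1, with fixI at 1.80 and fixP at 2.66 (camera 0.013, estimated 0.518), and 9 rose and 5 fell against high-light malate. Alternative nitrogenase genes rose in 7 of 13 and fell in 1, with vnfE at 2.94 (camera 0.0126, estimated 0.241), or 6 and 1 against high-light malate. Of the ribosomal protein genes 36 of 50 fell and 2 rose, 37 and 3 adjusted over the list alone (camera 1.32e-05, estimated 0.241), but 18 rose and 13 fell against high-light malate. In complex I 17 of 27 fell and 1 rose with nuoM2 at -1.34 (camera 0.000575, estimated 0.241), but 11 rose and 9 fell against high-light malate. Haem and cobalamin genes fell in 20 of 27 and rose in 3, with hemN1 at 1.64 (camera 0.0022, estimated 0.329), while 8 rose and 2 fell against high-light malate. Iron and metal uptake genes fell in 11 of 18 and rose in 3 with feoB at -1.27 (camera 0.0158, estimated 0.241), and benzoate degradation genes fell in 18 of 29 and rose in 5 with hbaG at -2.27 (camera 0.0154, estimated 0.162). Against high-light malate these were 10 and 3, and 25 and 0. Flagellar and chemotaxis genes rose in 19 of 39 and fell in 6 (camera 0.0273, estimated 0.329), and their median turns from 0.28 to -0.20 with library totals alone, by the shift that all genes share, while 18 rose and 11 fell against high-light malate. Where not given, counts adjusted over the list alone were the same. In all 2974 genes differed, 1351 higher and 1623 lower. With library totals alone the balance was 648 to 2943 and the median of all genes moved from -0.071 to -0.55, so changes are relative to the TMM scaling.

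The light response differed between strains in 537 genes, with a positive interaction in 319 and a negative one in 218. LH2 genes responded less in 5 of 10 cases, 7 adjusted over the list alone, with pucBd at -2.68 ± 0.365, pucAd at -2.64 and pucBc at -2.14 (camera 3.19e-07, estimated 0.0955). In the deletion strain these genes were higher in high-light succinate (pucBd 244 ± 33.9 CPM against 57.1 ± 4.4, SD, n = 2 each) and not called as different in low-light succinate. The smallest p belonged to RPA1685 (1.85 ± 0.127, adjusted p 9.57e-08), aroG1 (-2.38 ± 0.18), RPA3054 (1.74), mexD2 RPA1498 (1.35) and RPA1845 (1.77). In low-light succinate the strain effect on RPA1685 and aroG1 was not called, and RPA3054, mexD2 RPA1498 and RPA1845 were less reduced than in high-light succinate. Among lists that fell in the wild type, the interaction was positive for 8 of 18 iron and metal uptake genes, 9 adjusted over the list alone, with exbB3 at 2.36 and fecR4 at 1.56 (camera 7.89e-07, estimated 0.0316). It was positive for 7 of 29 benzoate degradation genes, 8 adjusted over the list alone, with hbaG at 1.15, a smaller fall than in the wild type (camera 0.00528, estimated 0.0316). Complex I had 7 of 27 higher, 11 adjusted over the list alone, with nuoM2 at 0.89 (camera 1.04e-05, estimated 0.115). Ribosomal proteins had 14 of 50 higher and 1 lower, 16 and 1 adjusted over the list alone, with rplF at 0.98 (camera 1.78e-07, estimated 0.16). Of the other lists, 3 of 21 hydrogenase genes, 3 of 8 acetate and glyoxylate genes and 1 of 10 ATP synthase genes were higher, 1 acetate and glyoxylate gene was lower, and 4 of 18 chaperone and protease genes were lower, with hspD at -1.35. Adjusted over the list alone these were 5 with 1 lower, 4, 1, 1 and 4 (camera 0.0246, 0.0114, 0.0034 and 0.0246, estimated 0.496, 0.132, 0.51 and 0.324). The 8 libraries alone gave 1037 genes. Without wild-type high-light replicate 2 the count was 351, without wild-type low-light replicate 2 346 and without deletion low-light replicate 2 327. In the 4 high-light libraries compared, nifD stood at 4932 to 7793 CPM.

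Carbon sources were compared in the wild type on PM medium at high light, with the 2 acetate libraries shared by both comparisons, which are not set against each other. On malate the largest increases over acetate were ilvJ (8787 ± 621 CPM against 68.1 ± 3.63, SD, n = 2 each, 7.01 ± 0.495, adjusted p 6.44e-10), RPA0538 (128-fold), RPA0744 (6.77), RPA3470 (6.67) and RPA3188 (6.61). The largest decreases were RPA2352 (-6.59), RPA2346 (-6.44), RPA2347 (-6.03), nifH1 (-5.95 ± 0.332) and RPA2359 (-5.81). In molybdenum nitrogenase 10 of 28 genes fell, 9 adjusted over the list alone, and 2 rose (camera 0.0263, estimated 0.5). The leading ones, nifH1, nifH2, nifH3 and nifB2, lie outside the nif stretch named above, and similar nifH copies may share reads. Within that stretch, nifD stood at 24.04 and 29.18 CPM on malate and 29.08 and 31.99 CPM on acetate. These values overlap, so the fall on this list does not describe nifD. Benzoate degradation genes rose in 28 of 29 cases although no benzoate was given, with hbaE at 6.30 and hbaG at 5.49 ± 0.118 (camera 8.14e-16, estimated 3.59e-06). Hydrogenase genes rose in 19 of 21 and fell in 1, with hypD at 2.45 (camera 4.2e-10, estimated 0.0441). In ribosomal proteins 48 of 50 genes fell, with rplW at -1.91 (camera 3.36e-15, estimated 0.0441), and complex I genes in 25 of 27, with nuoH1 at -1.09 (camera 8.75e-08, estimated 0.0441). All 10 ATP synthase genes fell (camera 0.00404, estimated 0.544), as did 9 of 12 citric acid cycle genes, with gltA at -1.29 (camera 0.00648, estimated 0.154), and 13 of 17 Calvin cycle genes with 1 higher, led by cbbA (-2.03) and cbbM (-2.01) (camera 0.00783, estimated 0.353). Haem and cobalamin genes fell in 23 of 27 and rose in 1, 2 adjusted over the list alone, with cobC at -1.83 (camera 0.000154, estimated 0.352). Other counts adjusted over the list alone were the same. In all 2926 genes differed, 1296 higher and 1630 lower, or 1493 and 1337 with library totals alone, which moves the median of all genes from -0.087 to 0.017.

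On benzoate, where the medium also held 10 mM bicarbonate, the genes of anaerobic benzoate degradation rose most over acetate. The benzoyl-CoA reductase genes badD (2893 ± 500 CPM against 4.89 ± 0.751, SD, n = 2 each, 9.21 ± 0.327, 593-fold, adjusted p 5.48e-14), badF (557-fold), badE (543-fold) and badG (427-fold) and hbaB (496-fold) led, and all 29 list members rose, 29 adjusted over the list alone, with a median of 6.67 (camera 2.7e-25, estimated 1.75e-07). The largest decreases were RPA2379 (-4.99 ± 0.361), RPA2378 (-4.49), RPA2346 (-4.21), RPA2380 (-4.16) and phyB5 (-3.97). All 10 LH2 genes rose, with pucAb at 2.88 (camera 4.64e-06, estimated 0.183), hydrogenase genes rose in 18 of 21 and fell in 1 (camera 6.41e-05, estimated 0.183), and pigment genes rose in 16 of 22 and fell in 2, with crtE at 2.13 (camera 0.00872, estimated 0.567). Ribosomal protein genes fell in 43 of 50 and rose in 5, with rpsK at -1.99 (camera 1.54e-09, estimated 0.183), and haem and cobalamin genes fell in 20 of 27, with cobF at -2.66 (camera 6.53e-05, estimated 0.304). Molybdenum nitrogenase genes fell in 18 of 28 and rose in 3, 19 and 3 adjusted over the list alone, with nifH4 at -2.05 (camera 0.00825, estimated 0.436), and iron and metal uptake genes fell in 12 of 18 and rose in 1, with exbD3 at -3.55 (camera 0.00634, estimated 0.183). Other counts adjusted over the list alone were the same. In all 3362 genes differed, 1538 higher and 1824 lower. Library totals alone moved the median of all genes from -0.079 to -0.11.

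In low light, succinate was compared with acetate in the wild type on NFM. The largest increases were RPA1704 (2545 ± 221 CPM against 38.3 ± 0.721, SD, n = 2 each, 6.05 ± 0.347, adjusted p 1.23e-10), RPA1703 (5.71), RPA0744 (5.58), nirA (4.38) and RPA3200 (4.25). The isocitrate lyase gene aceA, which acetate use through the glyoxylate cycle requires, went from 12310 ± 2510 to 1149 ± 7.17 CPM (-3.42 ± 0.229, 10.7-fold, adjusted p 9.76e-10). The other large decreases were RPA3383 (-3.96), RPA1430 (-3.31), RPA2321 (-3.30) and RPA4302 (-3.27). Benzoate degradation genes rose in 26 of 29 cases, 26 adjusted over the list alone, with hbaE at 3.41 and badA at 2.42 (camera 1.2e-11, estimated 2.33e-05). Hydrogenase genes rose in 19 of 21 and fell in 1, 20 and 1 adjusted over the list alone, with hupF at 1.96 (camera 2.09e-08, estimated 0.0881). Complex I genes rose in 17 of 27, 17 adjusted over the list alone, with nuoE1 at 0.85 (camera 0.000301, estimated 0.247). Ribosomal protein genes fell in 35 of 50 and rose in 1, also adjusted over the list alone, with rpmD at -1.52 (camera 1.7e-10, estimated 0.155). In all 2427 genes differed, 1283 higher and 1144 lower, and library totals alone moved the median of all genes from 0.020 to 0.11.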

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

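The test on random splits of the libraries and the low-light-like comparison on benzoate were chosen before the result was seen, and the other tests of this part after it, those of light intensity and of single benzoate libraries in place of earlier ones whose outcome was fixed by construction.

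The strain effect differed between conditions in 2643 genes. The largest F were those of RPA0745 (212.2), RPA0744 (106.9), RPA1685 (106.8), aroG1 (93.28) and RPA4682 (88.27), each a difference between conditions in the effect of the deletion. The response to the nitrogen condition differed between strains in 193 genes, with RPA4099 at 2.67, hypD at 1.101, RPA4098 at 3.156, mexD2 RPA2736 at -0.9276 and hoxA at 1.031. The response to light differed between strains in 537 genes, with RPA1685 at 1.854, aroG1 at -2.377, RPA3054 at 1.739, mexD2 RPA1498 at 1.351 and RPA1845 at 1.771.

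Many genes were called for the average strain effect. If a random grouping of libraries were the cause, other splits of the libraries within conditions would call as many. Of 100 splits 1, the real one, reached 2392 genes, and the highest other split gave 929. A random grouping is thus an unlikely cause of the count. Other splits mostly place libraries of both strains in a group, which widens the spread within groups. Whether the libraries of a group came from separate cultures is not stated, so the splits cannot exclude differences between cultures. They also do not test what the strains differ in besides regS and regR.

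The strain effect was smaller in low light. A larger replicate error there would make it look smaller in calls alone, but the spread of the effect freed of replicate error was 0.274 and 0.32 in low light against 0.511 to 0.773 in high light (highest over lowest 0.626). Library totals were close, with a ratio of medians of 0.919. The median TMM factor was 0.768 in low light and 1.105 in high light, so most genes had lower depth there than totals show. Lower depth therefore stays open as a part of the smaller count of calls. NFM malate at high light is labelled nitrogen-fixing as both low-light conditions are. Its lowest count with 1 library left out was 2.85 times the highest in low light, and its spread freed of error was 0.511. The nitrogen condition alone thus did not make the effect as small on malate. The carbon source differs from both low-light conditions, so a part of the nitrogen condition stays open. Of 340 genes called in low-light acetate, 59.4% had a larger effect in high-light than in low-light succinate (medians 0.3 and 0.269). These genes were picked for an effect in low light, so the share cannot measure how far the effect shrinks there. Between the 2 succinate conditions the spread freed of error was 0.599 in high and 0.32 in low light. Called genes that changed at least 2-fold were 360 and 64. The effect was thus smaller in low light on the same carbon source. The nitrogen-fixing labels of this pair differ, so light intensity as the cause stays open.

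The strain effect was largest on benzoate. Whether it rests on 1 of the poorly matching deletion libraries stays open, since the spread of the weaker one alone was 0.76 against at most 0.599 in other conditions, but 0.654 times the latter with all of the replicate difference taken off as error. The 4 benzoate libraries fitted alone gave 525, so the larger count may rest on borrowing the smaller spread of other groups. Across genes, which are not independent replicates, the effect correlated with the low-light response of the wild type (r 0.451, against 0.328 on PM acetate, 0.345 on PM malate, 0.214 on NFM malate and 0.123 in low-light acetate, differences not tested). With deletion replicate 1 or 2 alone r was 0.427 and 0.445, and 0.434 without the RPA3009 to RPA3013 cluster. The deletion strain on benzoate may thus resemble low-light cells in part. Terminal oxidase genes mostly rose in both comparisons. LH2 genes mostly rose in low light, while on benzoate more of them fell than rose. The nitrogen-fixing labels of the light comparison also differ.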

How the results depend on the processing

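No tests were added to this part after the result was seen, except the alternatives named as added.

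RLE size factors, library totals alone, no low-count filter and the added removal of rnpB, tmRNA and ffs left each count of called genes within 1.5 times its value, though library totals moved the balance of higher and lower genes. DESeq2 did so except for the nitrogen condition by strain (314 against 193, the cause was not tested). With the added removal of the benzoate libraries the average strain effect gave 2421 genes, 1960 of them shared with the 2392, and the interaction with condition gave 2573, 2064 of them shared with the 2643.

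Fits on only the 4 libraries of a condition gave 2420 genes on PM acetate (1484 with all libraries), 402 on PM malate (785), 525 on benzoate (2667), 565 in low-light acetate (342) and 671 in low-light succinate (288). The 8 libraries of the light by strain comparison alone gave 1037 (537). By construction such a fit uses the spread of those groups alone, which replicate SDs of 0.191 in wild-type PM acetate and 0.651 in deletion benzoate illustrate.

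Replicate number as a block gave 172 genes in low-light acetate against 342, the cause was not tested. Whether replicate numbers pair libraries of both strains is not stated. With the block the adjusted p of cbbX on PM malate was 0.0644 and that of RPA1741 in low-light succinate 0.0618.

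Leaving out 1 library gave 2251 to 2903 genes for the average strain effect, 917 to 1007 on PM acetate, 520 to 681 on PM malate, 2197 to 3095 on benzoate, 874 to 1018 on NFM succinate, 552 to 684 on NFM malate, 86 to 194 in low-light acetate and 147 to 174 in low-light succinate. It gave 2283 to 3607 for the interaction with condition, 864 to 1069 for nitrogen, 2510 to 2546 for light, 69 to 228 for nitrogen by strain and 327 to 422 for light by strain. Counts mostly fell. They rose only without a benzoate or PM malate library of the deletion strain, the groups whose replicates differed most (SD 0.651 and 0.324). The causes were not tested.

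Over 22 lists and 15 comparisons 109 pairs were called, 17 with the estimated correlation, 173 with fry, which asks a different question, 108 with RLE size factors and 102 to 114 without 1 library. For 342 pairs of named gene and comparison, 5310 alternatives were computed. The call was kept in 5209, lost in 101 (32 pairs) and reversed in 0. Each pair was called to begin with, so none could be gained. The pairs include the largest changes and the deleted genes, so these shares do not speak for other calls. On the 4 PM malate libraries alone cbbS, cbbX, cbbL, RPA1562 and RPA3568 were not called (adjusted p 0.142, 0.153, 0.116, 0.203 and 0.0536). With 2 libraries per group, a 1.5-fold change in low-light succinate was recovered in 62% of simulated genes, so changes of that size there can be missed at this replication.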

Other observations

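The test of this part was chosen after the result was seen.

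Of the 66 genes other than regR and regS that were called in 1 direction in all 7 conditions, 45.5% had an adjacent locus in the set. Random sets of the same size gave a median of 3.03%, a 95th percentile of 9.09% and a highest value of 16.7% over 10000 draws. Adjacent loci such as RPA1845 to RPA1849, RPA1258 to RPA1260, mexC1 with mexD2 RPA1498, and hflK with hflC may therefore be transcribed together, so the number of separate regulatory events is likely lower than the number of genes. Transcription units were not available to test this.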
